A study of Homo sapiens with 6 samples.

How the data were processed

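RNA from flash-frozen pituitary adenoma and normal pituitary tissue was measured by RNA sequencing in 6 libraries. Per the labels' protocols, RNA was extracted with a phenol reagent and spin columns, and libraries were made with a kit that does not mark strand. The protocol names both poly(A) isolation and ribosomal RNA depletion, so which of them was used is open. Per the submitters' processing notes, FastQC 0.11.8, Trimmomatic 0.39, edgeR and the build GRCh38 were used. The aligner, the counting tool and the annotation release are not given in the sources used here.

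The deposited tables hold, per the file headers, whole-number counts of reads for 60448 genes: total and unique gene reads, exon reads, intron reads and reads across exon junctions. By their names, the unique counts leave out reads that match several places and the total counts keep them. The tables also hold values that are TPM per the file headers, deposited by the authors. How they were computed is not given in the sources used here. Depth ran from 35244850 to 56370492 gene reads per library. Reads counted to introns exceeded those counted to exons in each library, so the gene counts include unspliced RNA. Reads of RNA components of the signal recognition particle (7SL) took 1.62% to 4.69% of gene reads, noncoding genes of the ribosomal RNA locus 0.645% to 5.10%, and mitochondrial genes 2.90% to 5.64%.

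Groups came from the labels. The title and the group tag agree for 3 normal and 2 adenoma libraries. They contradict each other for 1 library, which was left out of the comparison and entered as adenoma and as normal in alternatives. Replicate numbers follow the order of deposit and pair nothing. Genes that can show a person's sex, 546 in all, were left out of every table. CPM values are counts scaled to a common total of the remaining gene reads of each library. Agreement between libraries was computed as the Pearson correlation of log2(CPM + 1) across genes of mean CPM of at least 1. Across genes, which are not independent replicates, normal replicates 1 and 2 correlated at 0.9887. Their counts still differed by 37.8 times the sampling noise (chi-square per degree of freedom over genes of at least 20 reads together), against 131 to 443 for every other pair. This excludes a single library sequenced again but not preparations from the same tissue or patient. They were counted as separate samples, as the labels list them.

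The comparison used edgeR 4.0.16 in R 4.3.3 on the total gene counts: filterByExpr with its default minimum count of 10, TMM normalization, glmQLFit and glmQLFTest without covariates, and Benjamini-Hochberg adjustment over the genes tested with a threshold of 0.05. The biological coefficient of variation was 0.339, on 3 residual degrees of freedom. Standard errors are the log2 fold change divided by the square root of the F statistic. DESeq2 1.42.0 (Wald test, after the same filterByExpr step) and limma 3.58.1 (trend, on log2(TPM + 1) of genes with a TPM of at least 1 in at least 2 libraries) were alternatives. DESeq2 gave no adjusted p for 904 genes, which were counted as not called. Alternatives were DESeq2 size factors, edgeR's robust option, no low-count filter, a stricter filter (CPM of at least 1 and at least 10 reads in at least 2 libraries), unique gene reads, exon reads, the library with contradicting labels in either group, an added log2 fold change limit of 1, and each library left out in turn. Further alternatives were chosen after the data had been seen: exon reads of protein-coding genes alone, DESeq2 with each library left out or with the further library, and a batch term for the set of libraries by share of 7SL RNA, parted at the largest gap in that share.

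Gene lists of 210 genes in 19 groups were fixed: corticotroph, somatotroph and lactotroph, gonadotroph and thyrotroph, pituitary stem and folliculostellate, posterior lobe pituicyte, endothelial, fibroblast and pericyte, macrophage, lymphocyte, red blood cell, cell proliferation, cell cycle regulators, glucocorticoid response, Cushing's disease genes and drug targets, secretory granule, unfolded protein response, immediate early, mitochondrial respiration, and histone deacetylases. The filter kept 197 of these genes. Each list was tested with fry for a common direction and for change in either direction, and with camera, which sets a list against all other genes, with its preset correlation of 0.01 and with an estimated correlation. List members were also adjusted over the list alone. The groups, the main test, the lists, the first set of alternatives and the rule for named genes were set before the data were examined.

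The rule named POMC, the first gene of each list, up to 4 members per list past the threshold, and the 10 largest increases and 10 largest decreases among called genes whose adenoma libraries all lie beyond all normal libraries, with an average log2 CPM of at least 3 and an approved-style symbol. Because edgeR called 0 genes over all genes, the members past the threshold were taken from the test adjusted over the list alone and the largest changes from the DESeq2 calls. Genes outside the rule, such as AVPR1B, GAL, GH2, POU1F1, RGS5, EGR2, EGR3, CDK1, SGK1, DRD2 and SSTR2, were chosen after their values had been seen.

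The fits were tested on simulated data, with counts drawn from the means, depths and dispersions of the 5 libraries. The dispersions were those edgeR estimated for each gene, and genes were drawn independently, unlike real ones. The changed genes were taken only among genes above a minimum mean read count, so recovery does not cover the least-read genes. Of 22680 genes in the fit, 68, 66 and 66 were given true log2 fold changes of 1, 2 and 4 in either direction. At these sizes edgeR recovered 4.4%, 51.5% and 87.9% of the changed genes, with 12 false among 107 calls. DESeq2 recovered 27.9%, 77.3% and 98.5%, with 104 false among 239 calls. Gene coordinates are those in the deposited tables.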

Results

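RNA was sequenced from pituitary tissue removed at surgery for Cushing's disease, a disorder in which a corticotroph adenoma of the pituitary releases excess adrenocorticotropic hormone (ACTH). By their labels, 3 libraries came from normal pituitary tissue and 2 from adenoma tissue. The group tag marks normal replicate 2 alone as adjacent tissue, and where the other normal tissue lay is not given per library. A further library is called normal in its title and adenoma in its group tag. It entered neither group, and its values are given on their own. Reads assigned to genes numbered 56370492, 35244850 and 48021106 in normal replicates 1 to 3, 46213897 and 42659572 in adenoma replicates 1 and 2, and 49649093 in the library with contradicting labels. Intron reads made up 56.7% to 61.6% of gene reads. The labels do not say which libraries share a patient, so p-values measure the spread between these samples only. The libraries also form 2 sets by their share of 7SL RNA, the abundant RNA of the signal recognition particle, which the labels do not name. Normal replicates 1 and 2 and adenoma replicate 2 held 3.31% to 4.69% of gene reads in it, and the other 3 libraries 1.62% to 1.76%. After these shares had been seen, edgeR was also fitted with the set as a term, and calls over a list that this changes are given beside it. Where an adenoma library was left out, the other stood alone, with the spread of the normal libraries assumed for it. A call kept in such a fit is weak support.

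The comparison of adenoma with normal tissue asks which genes differ between the tumour and normal pituitary tissue. The corticotroph genes POMC, PCSK1, TBX19 and CRHR1 rose in the adenoma libraries. POMC, which encodes the precursor of ACTH, averaged 765 ± 635 CPM (gene reads scaled to a common library total; SD, n = 2) in adenoma and 142 ± 50.2 (SD, n = 3) in normal tissue, a fitted difference of 5.55-fold. Among the genes of growth hormone cells, GHRHR fell from 420 ± 29.9 CPM (SD, n = 3) to 89.9 ± 58.7 (SD, n = 2) and DLK1 from 271 ± 51.7 to 109 ± 11.6, while the prolactin gene PRL rose from 7410 ± 4323 to 23792 ± 7974. HDAC9, a class IIa histone deacetylase, rose from 231 ± 21.4 to 612 ± 93.2 CPM. These calls come from edgeR's quasi-likelihood test adjusted over the gene list alone. Adjusted over all 23115 genes tested, edgeR called 0 genes higher and 0 lower (lowest adjusted p = 0.0686), and DESeq2 called 833. By edgeR 2248 genes had an unadjusted p under 0.05. Chance gives 1156 on average, but genes are not independent, and other groupings of the same 5 libraries gave 367 to 2076.

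**Figure D1:**
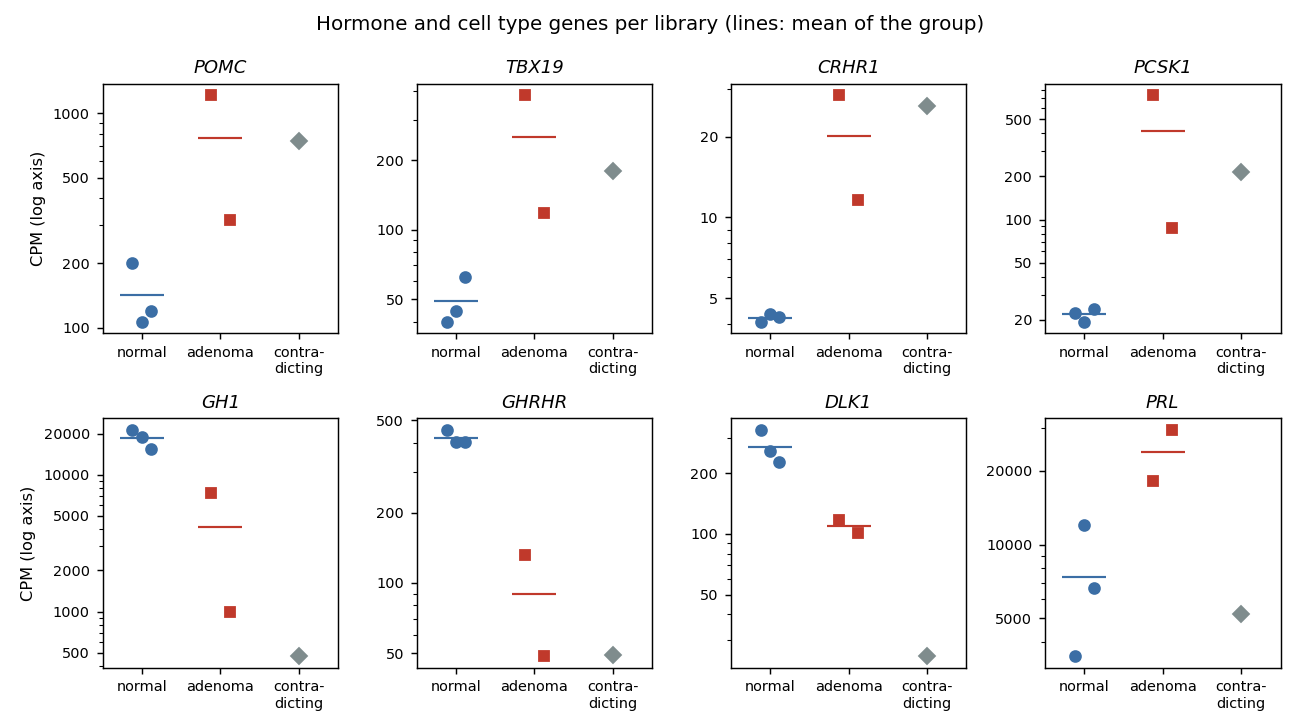
Points show the CPM (log axis) of POMC, TBX19, CRHR1, PCSK1, GH1, GHRHR, DLK1 and PRL in each normal library, each adenoma library and the library with contradicting labels, and lines show the mean of a group. Both adenoma libraries lie above all 3 normal libraries for the corticotroph genes and PRL and below them for GH1, GHRHR and DLK1.

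POMC lies on the minus strand of chromosome 2 from position 25160853 to 25168903 of GRCh38 (ENSG00000115138). It was measured at 199, 107 and 119 CPM in normal replicates 1 to 3 and at 1214 and 316 CPM in adenoma replicates 1 and 2. Of the 10 corticotroph genes tested, 4 rose and 0 fell adjusted over the list alone, and 0 passed over all genes. The log2 fold changes were 4.28 ± 0.79 (SE) for PCSK1, a prohormone convertase that cleaves the POMC precursor, and 2.47 ± 0.55 for POMC. They were 2.40 ± 0.46 for TBX19, the T-box factor of the corticotroph lineage, and 2.29 ± 0.37 for CRHR1, the receptor of corticotropin-releasing hormone. Their adjusted p over the list alone was 0.00944 for POMC and 0.00614 for the others (edgeR). Adenoma replicate 1 held more of each than adenoma replicate 2. Without replicate 1 the log2 fold changes were 2.06 for PCSK1, 1.22 for POMC, 1.34 for TBX19 and 1.53 for CRHR1, and each call held with every library left out in turn (POMC without adenoma replicate 1, adjusted p = 0.0498). Over all genes DESeq2 called POMC (adjusted p = 0.000918), but not without adenoma replicate 1 (log2 fold change 1.23, adjusted p = 0.0611). The vasopressin receptor gene AVPR1B, at 1.77 ± 0.74 (adjusted p = 0.107), and GAL, at 0.54 ± 0.42, did not pass. As a set the list was called higher by camera with its preset correlation (adjusted p = 2.97e-06). With an estimated correlation the adjusted p was 0.244, and fry gave 0.421. The estimated correlation of -0.026 lay below the preset of 0.01, so correlated genes do not account for the larger p.

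Of the 10 somatotroph and lactotroph genes tested, 3 fell, 1 rose and 6 did not pass adjusted over the list alone, and 0 passed over all genes. GHRHR, the receptor of growth hormone-releasing hormone, fell by 2.18 ± 0.41 (SE) on the log2 scale, the retinoid receptor gene RXRG by 1.45 ± 0.29 and DLK1 by 1.26 ± 0.21 (adjusted p = 0.00747 for each, edgeR). These calls held with each library left out in turn. GH1, the growth hormone gene, was read at 21335, 18930 and 15519 CPM in the normal libraries and at 7303 and 997 CPM in adenoma replicates 1 and 2. Its log2 fold change of -2.13 ± 0.78 did not pass over the list (adjusted p = 0.0648). It was -4.16 without adenoma replicate 1 and -1.33 without adenoma replicate 2, so the adenoma libraries differ in its size. GH1 passed with the 7SL set as a term, at -2.79 ± 0.89 (adjusted p = 0.0496). GH2, a near-identical paralog that can share reads with GH1, had a log2 fold change of -2.05 ± 1.02. PRL, on the minus strand of chromosome 6 from 22287244 to 22297501, rose by 1.74 ± 0.53 (adjusted p = 0.0405). The PRL call was lost without adenoma replicate 2 (adjusted p = 0.12), normal replicate 1 (0.0889) or normal replicate 3 (0.085). POU1F1, the transcription factor shared by both lineages, had a log2 fold change of -0.11 ± 0.25. Camera called the list lower with its preset correlation (adjusted p = 0.00242), and the adjusted p was 0.429 with an estimated correlation of 0.017.

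Other pituitary cell types gave no call at the gene level. In the gonadotroph and thyrotroph list 0 of 10 genes passed adjusted over the list alone, and LHB had a log2 fold change of -1.31 ± 1.47 (SE). The median of this list was -0.24, whereas the direction given by fry was up (adjusted p = 0.979). In the stem and folliculostellate list 0 of 10 passed. SOX2 stood at -0.18 ± 0.26, and the median of -0.10 and the mean of 0.23 differ in sign. FXYD1 passed with the 7SL set as a term (2.30 ± 0.46, adjusted p = 0.0391). It had few reads, at 0.0711 to 0.459 CPM in normal tissue and 1.82 and 0.587 in adenoma replicates 1 and 2. DESeq2 with the same term did not call it over all genes (adjusted p = 0.0658). In the pituicyte list 0 of 8 passed, GFAP stood at 0.56 ± 0.73, and the median was -0.03 where fry gave the upward direction (adjusted p = 0.979).

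In the lists of vessel, stromal and macrophage genes, VWF and ACTA2 rose, and most other genes above the normal libraries were so in adenoma replicate 2 alone. Of 9 endothelial genes, VWF, the clotting factor stored in endothelial cells, rose by 2.19 ± 0.35 (SE) on the log2 scale (adjusted p = 0.00573 over the list alone, edgeR), and PECAM1 stood at 0.46 ± 0.63. Of 10 fibroblast and pericyte genes, ACTA2, the smooth muscle actin gene, rose by 1.23 ± 0.25 (adjusted p = 0.0254), while COL1A1 stood at -0.10 ± 0.42 and the pericyte gene RGS5 at 1.23 ± 0.34 (adjusted p = 0.0504). The ACTA2 call was lost without adenoma replicate 2 (adjusted p = 0.179), normal replicate 1 (0.0653) or normal replicate 2 (0.0861). Of 10 macrophage genes, 10 had a positive log2 fold change and 0 passed, with CD68 at 0.71 ± 0.31. Adenoma replicate 2 lay above all normal libraries in 5 of the 9 endothelial, 9 of the 10 fibroblast and pericyte and 9 of the 10 macrophage genes. For adenoma replicate 1 these counts were 1, 2 and 1. With the 7SL set as a term, FLT1 (adjusted p = 0.0053) and TEK (0.0298) passed over the endothelial list, and MRC1 (0.0207) over the macrophage list. So did RGS5 and COL3A1 (0.012 each), PDGFRB (0.0138), COL6A3 (0.0188) and COL1A2 (0.022) over the fibroblast and pericyte list, all higher in adenoma. Within its 7SL set adenoma replicate 1 stood against normal replicate 3 alone, the lowest normal library in each of these genes. Adenoma replicate 1 lay above all normal libraries only in RGS5 (202 CPM against at most 117). COL6A3, for example, read 4.89 CPM there, against 7.80, 5.94 and 2.25 in normal replicates 1 to 3. Camera called the 3 lists higher with its preset correlation, with adjusted p of 0.023 for endothelial, 0.00019 for fibroblast and pericyte and 0.0232 for macrophage genes. With an estimated correlation the adjusted p was 0.85, 0.655 and 0.85. Without adenoma replicate 2 camera's adjusted p was 0.964 for endothelial and macrophage genes, with medians of -0.23 and -0.11, and 0.5955 for fibroblast and pericyte genes. Without normal replicate 3 it was 0.581 for endothelial and 0.427 for macrophage genes.

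Blood cell lists gave no call. In the lymphocyte list 0 of 6 tested genes passed and CD3D had too few reads to be tested. In the red blood cell list 0 of 6 passed, and HBA1 stood at -1.46 ± 1.68 (SE). The medians were -0.08 and -0.17, against an upward direction by fry (adjusted p = 0.979 for each).

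Genes of secretion and of the endoplasmic reticulum were also compared. Of 12 secretory granule genes, PAM, which amidates peptide hormones, rose by 0.93 ± 0.19 (SE) on the log2 scale and the synaptotagmin gene SYT1 by 0.79 ± 0.20 (adjusted p = 0.0261 and 0.0438 over the list alone, edgeR), whereas CHGA stood at -0.56 ± 0.26 (-0.98 without adenoma replicate 1 and -0.25 without adenoma replicate 2). Fry called this list for change in either direction (adjusted p = 0.00846), and camera called it higher with its preset correlation (adjusted p = 0.0319; 0.655 with an estimated correlation). Camera's adjusted p for it was 0.254 with the 7SL set as a term and 0.405 without normal replicate 3. The median of the list was 0.49, and 0.22 without adenoma replicate 1. The PAM call was lost without normal replicate 1 (adjusted p = 0.0676) or 2 (0.0721), and that of SYT1 was kept only without adenoma replicate 1, with 0.05995 to 0.1205 in the other fits (log2 fold change 0.49 without adenoma replicate 2). With the 7SL set as a term the convertase gene PCSK2 passed as lower (-2.02 ± 0.21, adjusted p = 0.00194) and SNAP25 as higher (0.59 ± 0.15, 0.0317). Of 12 unfolded protein response genes, the stress factor gene ATF3 rose by 2.90 ± 0.50 (adjusted p = 0.0116) and HSPA5 stood at 0.53 ± 0.22 (0.22 without adenoma replicate 1). The ATF3 call was lost without adenoma replicate 1 (adjusted p = 0.0528) or normal replicate 1 (0.0588). Camera called the list higher (adjusted p = 0.000142; 0.655 with an estimated correlation, and 0.241 with the preset correlation without adenoma replicate 1). Adenoma replicate 1 lay above all normal libraries in 10 of these 12 genes and adenoma replicate 2 in 5.

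Immediate early genes, which respond to stimulation and handling within minutes, had the lowest camera p of the 19 lists (adjusted p = 1.19e-07 with the preset correlation, 0.655 with an estimated correlation). Of the 12 genes tested, 11 had a positive log2 fold change and 0 passed adjusted over the list alone. With the 7SL set as a term 8 of them passed as higher: FOS, EGR2, EGR3, IER3, NR4A1 and NR4A3 (adjusted p = 0.0142 each), JUN (0.0207) and FOSB (0.0305). Normal replicate 3 was low in this list, with FOS at 6.45 CPM against 39.6 and 35.2 in normal replicates 1 and 2 and EGR1 at 25.6 against 105 and 106. The median log2 ratio was 2.54 within the 7SL set that holds it and 0.92 within the other, and the median of the fit fell from 1.26 to 0.88 without it. Without the 7SL term FOS stood at 1.88 ± 0.67 (SE), EGR2 at 1.89 ± 0.52 and EGR3 at 2.52 ± 0.63. Adenoma replicates 1 and 2 lay above all normal libraries in 9 and 10 of the 12 genes.

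Of 11 proliferation genes 0 passed adjusted over the list alone, although 10 had a positive log2 fold change and adenoma replicate 1 lay above all normal libraries in 10. MKI67 was at 4.40 CPM in adenoma replicate 1 and 1.10 in adenoma replicate 2, against 0.814 to 1.12 in normal tissue. CDK1 stood at -1.75 ± 0.45 (SE), and with the 7SL set as a term it passed as lower (-1.95 ± 0.23, adjusted p = 0.00376). Of 11 cell cycle regulators, CCND1, the cyclin D1 gene, rose by 0.85 ± 0.19 (adjusted p = 0.0444), a call lost in each of the 5 fits without a library (adjusted p from 0.063 to 0.256) and with the 7SL set as a term (0.0892). CDKN1A stood at 0.13 ± 0.25. In the glucocorticoid response list 0 of 12 genes passed, with FKBP5 at -0.13 ± 0.36 and SGK1 at 1.08 ± 0.28. CRISPLD2 passed as higher with the 7SL set as a term (2.05 ± 0.34, adjusted p = 0.0204). In the list of Cushing's disease genes and drug targets 0 of 14 passed. The glucocorticoid receptor gene NR3C1 stood at -0.12 ± 0.19, the dopamine receptor gene DRD2 at 0.92 ± 0.43 and the somatostatin receptor gene SSTR2 at -0.54 ± 0.43. DRD2 passed as higher with the 7SL set as a term (1.11 ± 0.18, adjusted p = 0.0179). It read 205 CPM in adenoma replicate 2, but adenoma replicate 1, at 110 CPM, lay within the normal range of 48.9 to 119 CPM. Within its 7SL set adenoma replicate 1 stood against normal replicate 3 alone, the lowest normal library. The library with contradicting labels read 16.6 CPM of DRD2. The median of this list was -0.08 and its mean 0.09. Of 12 mitochondrial respiration genes 0 passed, with MT-ND1 at -0.51 ± 0.22.

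HDAC9 lies on the plus strand of chromosome 7 from 18086949 to 19002416. Of 12 histone deacetylase genes, HDAC9 alone passed adjusted over the list alone, with a log2 fold change of 1.46 ± 0.16 (SE; adjusted p = 0.00104, edgeR). The call held with each library left out in turn. HDAC1 stood at -0.37 ± 0.16. The list's median was -0.14 and its direction by fry was up (adjusted p = 0.979). For change in either direction fry gave an adjusted p of 0.0201. Over the 19 lists, 12 of 197 genes tested rose and 3 fell adjusted over the list alone, in 8 lists, and 0 passed over all genes. Fry called 0 lists for direction, camera called 8 with its preset correlation and 0 with an estimated correlation.

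**Figure D2:**
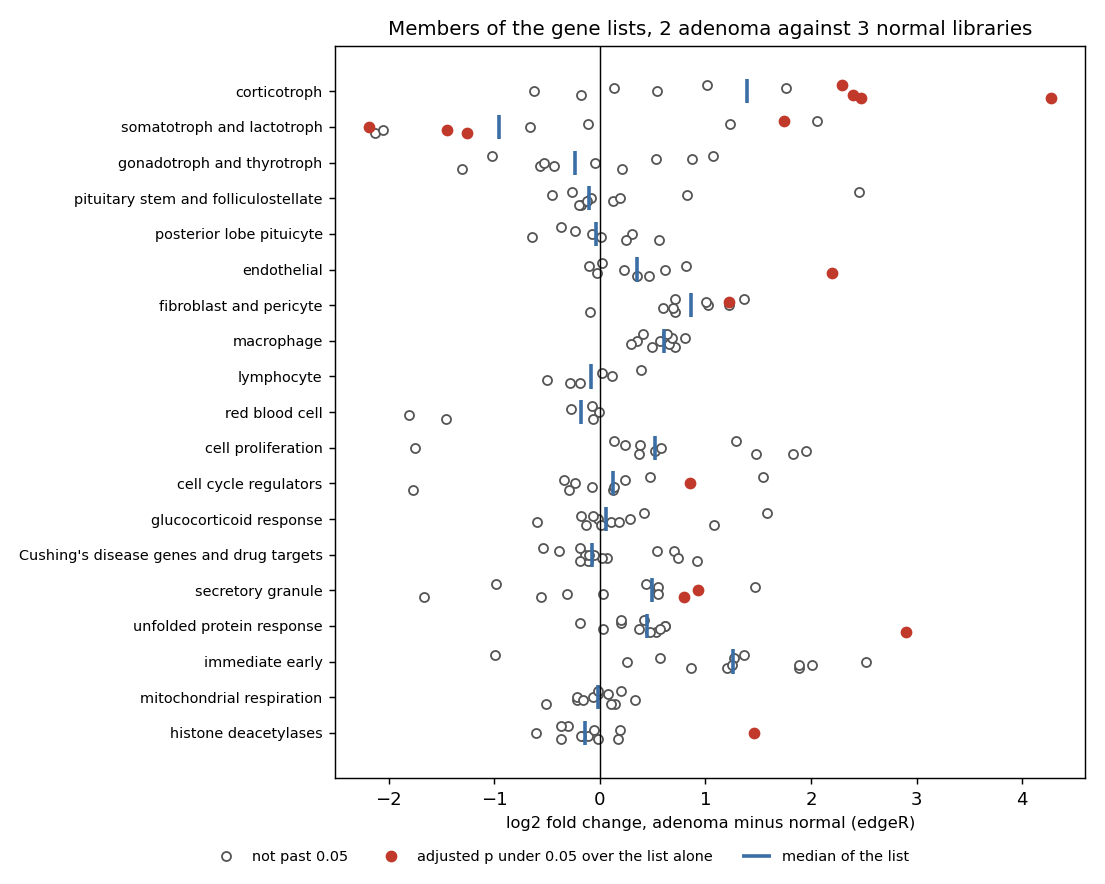
Each point is the edgeR log2 fold change (adenoma minus normal, horizontal axis) of a gene in the list named on the vertical axis, filled where the adjusted p over the list alone is under 0.05, and each bar is the median of a list. The corticotroph median is 1.39 and the somatotroph and lactotroph median -0.96, with PRL on the other side of 0 at 1.74.

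Over all genes, DESeq2 called 462 genes higher and 371 lower in adenoma. In counts simulated with edgeR's dispersions for 2 against 3 libraries, 104 of the 239 DESeq2 calls were false, against 12 of 107 for edgeR. The DESeq2 calls are therefore less certain than their adjusted p states. Since edgeR called 0 genes, the largest changes were taken from the DESeq2 calls after the values had been seen, and the log2 fold changes given for them are from edgeR. LINC01035, a long noncoding RNA on chromosome 1 from 188905688 to 189037262, stood at 13.2 and 38.2 CPM in adenoma replicates 1 and 2 and at 0.0417 to 0.199 CPM in normal tissue. Its log2 fold change was 7.74 ± 0.72 (SE; adjusted p = 5.72e-26, DESeq2). ST8SIA1, which encodes the ganglioside GD3 synthase, had a log2 fold change of 6.36 ± 0.88, at 198 and 25.4 CPM in adenoma and 0.897 to 1.70 CPM in normal tissue. These 2 genes, PCSK1 and the noncoding RNA PART1 (5.20 ± 1.03, and 2.48 without adenoma replicate 1) were called by DESeq2 with every library left out in turn.

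Several other DESeq2 calls rested on a single adenoma library. CACNA1E, a calcium channel gene, stood at 116 CPM in adenoma replicate 1 and 2.56 in adenoma replicate 2, ANGPT2, which encodes angiopoietin-2, at 36.5 and 1.60, and TBX15 at 95.1 and 3.78. Without adenoma replicate 1 their log2 fold changes were 0.48, 1.06 and 0.85, with adjusted p of 0.9997, 0.787 and 0.744 by DESeq2, and their calls were also lost without any of the normal libraries (adjusted p from 0.0986 to 0.244). The immunoglobulin gene IGKC stood at 1.58 CPM in adenoma replicate 1 and 47.2 in adenoma replicate 2 (log2 fold change 1.14 and adjusted p = 0.863 without the latter), and its call was lost without any of the normal libraries (adjusted p from 0.138 to 0.233). NAALADL2-AS2 stood at 78.0 and 3.78 CPM, with a log2 fold change of 1.93 (adjusted p = 0.551) without adenoma replicate 1. It was also not called without normal replicate 1 (0.124) or 2 (0.209). As an antisense gene read without strand, it cannot be parted from the gene it overlaps.

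P3H2 stood at 659 and 50.2 CPM in adenoma replicates 1 and 2. Its log2 fold change was 1.38 without adenoma replicate 1 and 5.05 without adenoma replicate 2. DESeq2 lost its call on leaving out any of the normal libraries (adjusted p from 0.0835 to 0.141).

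Genes with the largest decreases by DESeq2 included GHRHR and GH1. The noncoding RNAs LINC00548 and LINC01608 had log2 fold changes of -2.50 ± 0.67 and -2.39 ± 0.46 (SE, edgeR). The histidine ammonia-lyase gene HAL stood at -2.26 ± 0.56, the ion exchanger gene SLC24A4 at -2.21 ± 0.50, the potassium channel subunit gene KCNMB2 at -2.11 ± 0.42 and the growth factor gene EGF at -2.02 ± 0.45. DESeq2 called these 6 and GHRHR with every library left out in turn, with LINC00548 at -4.17 and HAL at -3.47 without adenoma replicate 1. RELN (-2.07 ± 0.53) was not called without adenoma replicate 1 (adjusted p = 0.0565), ACADL (-2.18 ± 0.73, and -1.16 without normal replicate 3) without either adenoma replicate (0.121 and 0.0992), and GH1 without any of the normal libraries (0.16 to 0.361). Both adenoma libraries lay above all normal libraries in 2099 genes and below them in 3674, together 25.0% of the genes tested. Chance gives 20% on average, and its spread over genes that are not independent was not estimated.

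The differences of POMC, PCSK1, TBX19, CRHR1, GHRHR, PRL and HDAC9 kept their direction within both 7SL sets, which was given beforehand. For these genes both adenoma libraries lie beyond all normal libraries, so only the sizes can inform. The low set holds 1 adenoma and 1 normal library, besides the library with contradicting labels, and the high set 1 and 2. Within the set low in 7SL RNA, the log2 ratio of adenoma to normal CPM was 3.35 for POMC, 4.95 for PCSK1, -1.62 for GHRHR, 1.44 for PRL and 1.41 for HDAC9. Within the set high in 7SL RNA it was 1.05, 2.06, -3.15, 1.92 and 1.32. With the set as a term in the edgeR fit, LINC01035 rose with an adjusted p of 0.0186 over all genes, and the fibroblast and pericyte list was called higher by fry (adjusted p = 0.0206). By camera with an estimated correlation its adjusted p in that fit was 0.3. Adjusted over the list alone, 31 genes rose and 6 fell, against 12 and 3 without the term. PRL passed over its list (adjusted p = 0.0479) but was no longer called by DESeq2 (0.53).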

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

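The tests in this part were chosen after the values had been seen. The library whose title says normal and whose group tag says adenoma entered no comparison, and 7 of its 10 corticotroph genes lay above all 3 normal libraries. POMC was at 739 CPM against at most 199 in normal tissue, TBX19 at 180 against 62.5, PCSK1 at 216 against 23.9 and CRHR1 at 25.9 against 4.35. AVPR1B was at 16.9 CPM against at most 9.89, LIFR at 207 against 128.5 (not higher in the adenoma libraries, at 64.0 and 79.7), and NEUROD1 at 2.24 against 2.19 (lower in the adenoma libraries, at 0.888 and 1.17). GH1 was at 470 CPM against at least 15519 in normal tissue, GHRHR at 48.9 against 402 and DLK1 at 24.8 against 227. PRL, at 5208 CPM, lay within the normal range and below both adenoma libraries. LINC01035, at 0.404 CPM, was far below both adenoma libraries (13.2 and 38.2) but above all normal ones (at most 0.199). Of the other largest increases by DESeq2, PCSK1, ST8SIA1, NAALADL2-AS2, PART1, ANGPT2 and P3H2 (114 CPM against at most 20.4) lay above all normal libraries. CACNA1E, TBX15 and IGKC did not. Of the other largest decreases, KCNMB2 (32.1 CPM against at least 433), SLC24A4, EGF, RELN, LINC00548 and LINC01608 lay below all normal libraries. HAL and ACADL lay within their range.

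In the somatotroph and lactotroph list 8 of 10 genes lay below all normal libraries, and in the pituicyte list 5 of 8 lay above them (adenoma replicates 1 and 2: 0 and 1), with COL25A1 at 882 CPM against at most 358. Mitochondrial respiration genes, which also move with tissue quality, lay above them in 11 of 12 (adenoma replicates: 4 and 1).

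Lower depth is argued against, since the library held 49.6 M gene reads where the shallowest normal library held 35.2 M. A normal gland of the same makeup was not decided: in the lists of 8 other cell types 37 of 69 genes lay outside the range of the normal libraries, where chance gives 50% among like libraries. They were 24 of 28 genes of gonadotroph and thyrotroph, stem and pituicyte lists and 13 of 41 of vessel, stromal and blood cells. In the 28 genes each normal replicate was also set against the range of the other normal replicates. Normal replicates 1, 2 and 3 lay outside it in 19, 10 and 27 of them. The library with contradicting labels lay outside the same ranges in 25, 26 and 25. It thus stood apart more often than normal replicates 1 and 2 but not more often than normal replicate 3. The range for normal replicate 3 comes from normal replicates 1 and 2, the most alike pair of libraries. Adenoma tissue as the group tag says, normal tissue from another part of the gland, for which the pituicyte genes may speak, and a difference in tissue quality all stay open. The library was not reassigned.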

How the results depend on the processing

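Batch-term fits, fits on exon reads of protein-coding genes and DESeq2 fits on other sets of libraries were chosen after the data had been seen. No paired analysis was possible because the labels do not link libraries to patients. Of 48 named genes besides POMC, 39 kept the sign of their log2 fold change in every alternative that gave them a value. Among the 19 alternatives, the log2 fold change limit gave no new values. Some genes were also absent from some fits, such as GFAP with the stricter filter and SOX2 with unique gene reads. The 10 largest increases and 10 largest decreases were picked with both adenoma libraries beyond all normal libraries. Leaving out a library therefore hardly tests their sign. With 2 adenoma libraries, simulated changes of 2 on the log2 scale were recovered in 51.5% of genes by edgeR, so many changes of that size can be missed.

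Against 0 genes higher and 0 lower by edgeR, DESeq2 called 462 and 371, the fit with no low-count filter 162 and 54, limma on log2 TPM 81 and 25, and the 7SL batch term 1 and 0. Size factors, the robust option, the stricter filter, unique or exon reads, protein-coding genes alone, and the further library in either group gave 0 and 0. A log2 fold change limit of 1 leaves 0 and 0 by construction. Leaving out a library gave 0 to 176 higher and 0 to 6 lower, with 176 and 3 without adenoma replicate 2, 9 and 6 without adenoma replicate 1, and 0 in the rest. With a lone adenoma library its spread is assumed to be that of the normal ones. DESeq2 gave 306 higher and 267 lower with the further library as adenoma (455 of 573 calls shared with the 833), 207 and 71 with it as normal, and 347 and 235 with it as adenoma and the batch term. With the batch term alone DESeq2 gave 615 and 397, with 685 of the 1012 shared. Leaving out a library gave DESeq2 235 to 698 higher and 125 to 420 lower. The causes were not tested.

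Adjusted over the list alone, 12 genes rose and 3 fell. DESeq2 gave 24 and 8, no filter 33 and 8, the batch term 31 and 6, the batch term with the further library as adenoma 26 higher, the further library as normal 3 and 1, and protein-coding exon reads 5 lower. Leaving out a library gave 9 to 20 and 3 to 9. POMC passed over all genes by DESeq2 (2.47, adjusted p = 0.000918) and with no filter (2.47, 0.0362). Its adjusted p ran from 0.000918 to 0.914 over the alternatives other than DESeq2 fits on other sets of libraries. By DESeq2 without a normal library it was 0.000357 to 0.0158. The POMC log2 fold change ran from 1.22 to 3.12 on leaving out a library, lowest without adenoma replicate 1. Against 0 lists called by fry for direction, the batch term gave 1, also with the further library as adenoma, and leaving out a library 0 to 2. For change in either direction fry called 2 lists. With the batch term it also called others, such as fibroblast and pericyte (adjusted p = 0.000286) and glucocorticoid response (0.0305). Camera called 6 to 9 lists over the alternatives. With the further library as normal it lost the somatotroph and lactotroph (adjusted p = 0.817) and endothelial lists (0.234), and with it as adenoma the macrophage (0.483) and secretory granule lists (0.571). It also lost the granule list with the batch term (0.254) and by limma (0.05385), and the macrophage list with protein-coding exon reads (0.052). The causes were not tested.

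Signs turned for 9 genes, none past the test over its list, and for the endothelial and macrophage medians, which camera had called higher (adjusted p = 0.023 and 0.0232). CDKN1A was -0.13 with exon reads, -0.042 by limma on TPM, -0.030 with the further library as normal and -0.15 with protein-coding exon reads. NR3C1 was 0.16 with exon reads, 0.25 by limma, 0.40 with the further library as adenoma, 0.14 with protein-coding exon reads and 0.16 with batch term and further library. LHB was 0.39 by limma, 1.15 with the batch term and 0.91 with batch term and further library. HBA1 was 0.32 by limma. COL1A1 was 0.29 with the further library as adenoma, 0.077 with the batch term and 0.38 with both. FKBP5 was 0.67 with the further library as adenoma and 0.059 with the batch term too, and SOX2 was 0.0075 with the further library as normal. On leaving out a library, with or without a turn, COL1A1 ran from -0.40 to 0.31, HBA1 from -2.48 to 2.42, SOX2 from -0.49 to 0.056, CDKN1A from -0.063 to 0.24, FKBP5 from -0.85 to 0.33, NR3C1 from -0.20 to 0.0083, LHB from -1.91 to -0.36, MKI67 from 0.18 to 2.13, CD68 from 0.46 to 0.97, CHGA from -0.98 to -0.25, HSPA5 from 0.22 to 0.77, GFAP from -0.33 to 1.08, PECAM1 from -0.043 to 0.96, the endothelial median from -0.23 to 0.82 and the macrophage median from -0.11 to 0.98. The causes were not tested.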

Other observations

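The tests of dilution, of endothelial cells and of other groupings of the libraries were chosen after the results had been seen. Genes of the BCL2 family, which control cell death, were compared as a list of 12 with pro-apoptotic members given a negative sign. MCL1, a survival gene, stood at 109 and 126 CPM in the adenoma libraries against 72.7 ± 9.40 (SD, n = 3) in normal tissue, with a log2 fold change of 0.75 ± 0.18 (SE; adjusted p = 0.257 by edgeR and 0.0416 by DESeq2). BCL2 stood at -0.16 ± 0.19, BCL2L1 at 0.38 ± 0.16 and PMAIP1, the gene of the pro-apoptotic protein NOXA, at 1.30 ± 0.76. PMAIP1 read 63.8 and 21.9 CPM in adenoma, 6.36, 11.2 and 36.5 CPM in normal tissue and 192 CPM in the library with contradicting labels. The hypothesis of a shift towards survival was not decided, since fry gave a p of 0.128 for the signed list and the signed mean was 0.115 ± 0.170 (SE over genes).

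PRL was higher in the adenoma libraries while GH1, GHRHR and DLK1 were lower. Reads shared between growth hormone paralogs are argued against by the uniquely placed reads, with which the GH1 log2 fold change was -2.13 ± 0.79 (SE). Abundant noncoding RNA is argued against by the exon reads of protein-coding genes, with which PRL stood at 1.67 ± 0.50 and GH1 at -2.24. Depth and abundant coding transcripts were not decided by that fit, since it keeps PRL and GH1 and both fits are scaled for depth. Dilution of normal hormone cells by tumour cells stays open for the genes that were lower, since the gonadotroph and thyrotroph median of -0.24 lies within the spread of that list between normal libraries (SD 0.746). The PRL call was itself lost in 3 of the 5 fits without a library, and a difference between patients or between parts of the gland may give this pattern.

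Immediate early genes had a median log2 fold change of 1.26 in the adenoma libraries. A response to tissue handling was not decided by 12 heat shock genes, whose median was 0.13 ± 0.051 (SE over genes), since handling can act without them and the stress genes ATF3 (2.90 ± 0.50) and the unfolded protein response list (camera adjusted p = 0.000142, or 0.655 with an estimated correlation) were higher too. A larger share of endothelial cells is argued against only weakly by the endothelial median of 0.36 ± 0.23 (SE over genes). The endothelial genes move together (estimated correlation 0.835), so this SE is too small. Their median ran from -0.23 to 0.82 on leaving out a library. With the 7SL set as a batch term the immediate early median was 1.64 ± 0.26 (SE over genes, which also move together). The direction within both sets was largely given beforehand, since adenoma replicates 1 and 2 lay above all normal libraries in 9 and 10 of the 12 genes. Only the size can inform, and normal replicate 3, low in these genes, weighs on it (0.92 within the set without that library). The difference between these sets is therefore argued against only weakly. A difference between tissues in the time from removal to freezing, which the labels do not record, may still account for the higher immediate early genes, as may tumour biology.

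Groupings of the libraries were also exchanged. For the 5 libraries there are 10 groupings of 2 against 3, too few for a share under 0.05. The real grouping gave 833 DESeq2 calls against at most 404 in the others, and 2248 genes at an unadjusted edgeR p under 0.05 against at most 2076, the highest in each case (1 of 10). With the library with contradicting labels as adenoma, 3 of 10 groupings of 3 against 3 gave at least the 1929 genes of the real grouping, again too few for a share under 0.05. By DESeq2 the real grouping of 3 against 3 gave 573 calls, against at most 435 in the others. The highest by edgeR, with 2493 genes, was the grouping that parts the libraries by their share of 7SL RNA. With that set as a batch term the real grouping gave 1737 genes.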
